A study of Mus musculus with 6 samples.

How the data were processed

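RNA of splenic B cells from 3 arthritic and 3 non-arthritic BALB/c mice was hybridised to 1-colour Agilent arrays, 1 array per mouse, per the labels. Groups and mouse numbers were taken from the sample titles, and each array is a different mouse. The deposited scanner files hold the spot intensity as a processed signal, which Agilent Feature Extraction had background-subtracted and detrended within the array, per the file headers, and which was not normalized between arrays. The version is 11.0.1.1 per the file headers and 9.1 per the submitters' processing notes. The same deposited files hold the median spot and background intensity without correction, and other columns with flags per spot, per the file headers. The authors' value table holds log2 values for 13655 probes. Set against the scanner values, each of its columns correlated at 0.9999972 or more with the quantile-normalized log2 processed signal, so its scale is log2 and it is not centred by probe. Its column medians were 7.72, 7.51 and 7.50 in non-arthritic mice 1, 2 and 3 and 7.51, 7.51 and 7.51 in arthritic mice 1, 2 and 3. How its probes were chosen is not given in the sources used here. All were well above background on at least 3 arrays. It holds 49 CUST probes and 13606 ASMM9PARTA probes numbered from 19489 to 45081, out of 13791 detected in that range, so as a family it is largely a block of IDs after a detection filter; 14214 other detected probes are outside it.

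Before the data were examined, the groups, the test, the alternatives, the rule for named genes and the gene lists were fixed. From each array, the log2 processed signal of non-control spots was taken minus its 75th percentile over those spots. Control spots (1319 of 62513) and 1200 spots of 20 negative probes were left out, and spots of one probe were averaged. Probes were kept when well above background on at least 3 of the 6 arrays, whatever the group, which left 27869. Each was tested with limma 3.58.1 (lmFit and eBayes, no covariate) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9. A probe not well above background on any array of a group has only a bound there. Its fold is the mean of the brighter group against, for each array of the dimmer group, the higher of its own signal and the lowest signal among probes well above background, as "at least" a given fold.

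The files hold probe IDs and do not pair them with gene names, and 0 IDs matched the RefSeq gene table of assembly GRCm38.p6. The planned unit, 1 probe per gene, was therefore replaced by the probe, and the gene lists and cell type markers could not be applied, so that neither the purity of the B cells nor any pathway was analysed here. The rule for named genes took genes past the threshold with non-overlapping groups, ranked by log2 fold change; the same ranking was used for probes, limited to 2 IDs in each direction. In place of the lists, 7 probe families were formed from the IDs and from membership in the authors' value table, after the data had been examined. Families were tested with limma's camera (preset correlation 0.01; also an estimated correlation) and fry, with Benjamini-Hochberg adjustment over the 7. Simulated data had the spread of these arrays and 50 changed probes per fold size among 27869. There the fit recovered 24% of 2-fold, 72% of 4-fold, 78% of 8-fold and 94% of 16-fold changes, and called 9 unchanged probes. Changed probes were a far smaller share of the simulated probes than the 8.63% called in the real data. The adjustment depends on that share, so these values describe the simulation and are not recovery or error rates of the real comparison. Rates with an array standing apart, as non-arthritic mouse 1 does, were not obtained separately.

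Alternatives were quantile normalization, median scaling, no filter, a filter on all 6 arrays, the authors' value table, an intensity trend, robust variance, array weights, flagged spots as missing, each array left out, a replicate block, and a 2-fold threshold. Normexp with an offset of 50 on the median signals, cyclic loess, the array row as a block, and the row of both groups alone were added after the data had been examined. Slide and scan were the same for all arrays, so neither was used as a block. The mean over the probes of a gene and normexp on mean signals were not run, because genes are not named and mean signals were not used here.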

Results

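Gene expression was measured in B cells purified by affinity from the spleens of 6 female BALB/c mice, with 1 one-colour Agilent array per mouse. In 3 mice, arthritis had been induced by immunization with human proteoglycan, a component of the cartilage matrix that provokes an autoimmune joint disease in this strain, and the cells were taken 10 days after the third injection. The other 3 mice were non-arthritic and, per their sample descriptions, had received adjuvant, with cells also taken at 10 days. The treatment protocol in the labels is the same text for all 6 mice and names immunization with proteoglycan only, so the labels do not settle what the non-arthritic mice received. Each array carried 59709 different probes after control and negative probes were set aside. The 75th percentile of the processed signal was 187.3, 110.7 and 108.9 in non-arthritic mice 1, 2 and 3, and 136.1, 134.4 and 144.1 in arthritic mice 1, 2 and 3. Between 42.65% and 47.55% of the probes were well above background on each array, no spot was saturated, and the number of arrays, 3 per group, limited the precision. Over 15 probes spotted 20 times, the median SD between spots of one array was 0.0568 on the log2 scale, against a median SD of 0.297 between mice of one group. The latter averages the variances of the 2 groups, includes non-arthritic mouse 1, and also holds technical differences between arrays.

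The arthritic mice resembled each other closely, and the non-arthritic mice did not. Across the 27869 probes detected on at least 3 arrays, the mean correlation with the other arrays of the same group was 0.993, 0.991 and 0.992 in arthritic mice 1, 2 and 3. Non-arthritic mice 2 and 3 correlated at 0.992 with each other, whereas non-arthritic mouse 1 correlated at 0.956 with each of them and at 0.938 on average with the arthritic mice. On the first principal component, which held 59.11% of the variance, non-arthritic mouse 1 lay at -131.3, non-arthritic mice 2 and 3 at -5.53 and -8.48, and the arthritic mice between 46.4 and 51.1. These correlations are across probes, which are not independent replicates.

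**Figure D1:**
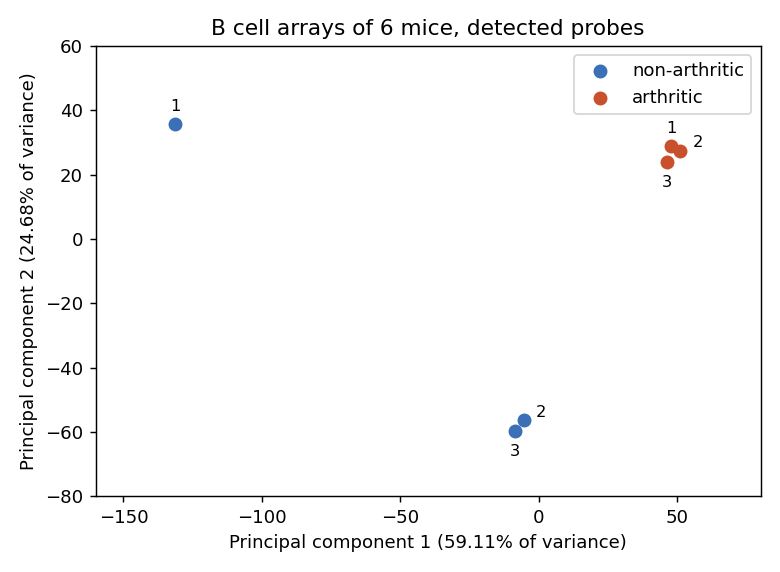
Each point is the array of 1 mouse, placed by the first and second principal components of the log2 scaled signal of detected probes (59.11% and 24.68% of the variance); numbers are mouse numbers within a group. The 3 arthritic mice lie together, non-arthritic mice 2 and 3 lie together, and non-arthritic mouse 1 lies at -131.3 on the first component.

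The comparison addresses which transcripts of splenic B cells differ between arthritic and non-arthritic mice. If only the arthritic mice received proteoglycan, as the sample descriptions give it, arthritis and immunization cannot be told apart here. The signal of 1209 probes was higher in the arthritic mice and that of 1196 was lower, together 8.63% of the probes tested. The files do not pair probes with gene names, so probes are given by their IDs. Probe ASMM9PARTA002280 rose at least 165.9-fold, from a log2 scaled signal of -4.76 ± 0.048 (SD, n = 3) that was not well above background in any non-arthritic mouse to 4.79 ± 0.090 (SD, n = 3), with a limma adjusted p of 7.79e-06. ASMM9PARTA004593 rose at least 32.5-fold, to 2.44 ± 0.055 (SD, n = 3), and likewise was not well above background in the non-arthritic mice (limma adjusted p = 8.94e-04). ASMM9PARTA007850 was at least 21.7-fold lower in the arthritic mice, where it was not well above background, than the 2.04 ± 1.09 (SD, n = 3) of the non-arthritic mice (limma adjusted p = 0.00357); without non-arthritic mouse 1 this bound was 14.1-fold.

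ASMM9PARTA033424 was at least 5.68-fold lower, from 0.11 ± 0.078 (SD, n = 3) in the non-arthritic mice to a signal not well above background in the arthritic mice (limma adjusted p = 8.94e-04). It was named by its fitted log2 difference and not by this bound. With probes not well above background in 1 group at their bound, 6 called probes were at least 8-fold lower. The wide SD of ASMM9PARTA007850 came with a value of 3.30 in non-arthritic mouse 1, against 1.44 and 1.39 in mice 2 and 3. All 4 probes kept adjusted p values under 0.05 with any 1 array left out. With the row of the array on its slide as a block in the fit, ASMM9PARTA004593, ASMM9PARTA007850 and ASMM9PARTA033424 had limma adjusted p values of 0.0625, 0.107 and 0.0625, with fitted log2 differences of 5.69, -6.38 and -4.92 against 5.74, -6.25 and -4.73 without the block, which are not measured sizes because the dimmer group has only a bound, and ASMM9PARTA002280 stayed past the threshold.

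**Figure D2:**
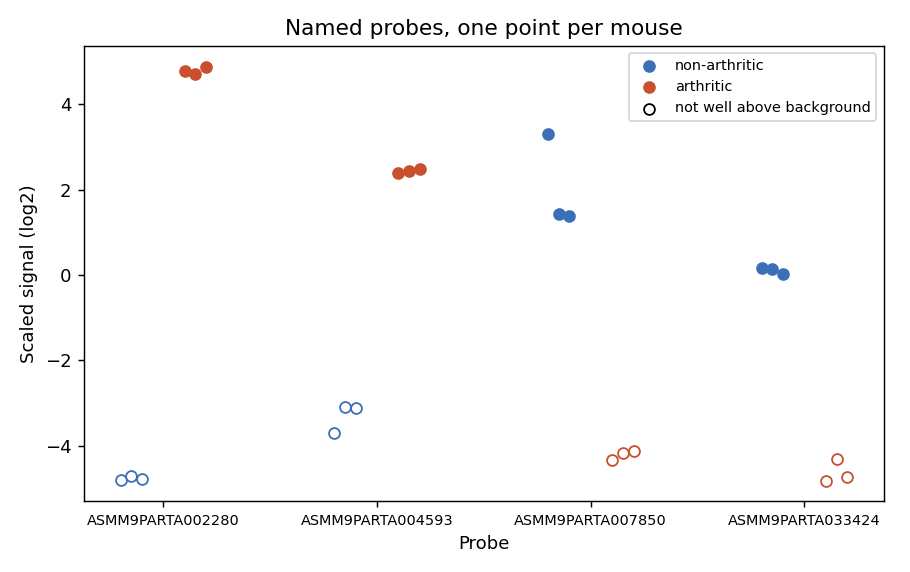
Log2 scaled signal (vertical axis) of the 4 named probes in each mouse; blue points are non-arthritic and orange points arthritic mice, and open points were not well above background. In all 4 probes the 3 mice of one group lie apart from the 3 of the other, and the dimmer group has only open points.

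Most of the called differences were moderate. Among called probes, the median fold was 2.36 for those higher and 2.09 for those lower, with probes not well above background in 1 group taken at their lower bound. On the same basis 841 probes were at least 2-fold higher and 673 at least 2-fold lower, 161 and 82 reached 4-fold, and 18 and 6 reached 8-fold. A set of 110 called probes was well above background in all 3 arthritic mice and in no non-arthritic mouse, and 157 showed the opposite. Among probes well above background on all 6 arrays, 1013 were higher and 902 lower, and the largest differences were 14.8-fold higher (log2 3.89, SE 0.244) and 16.4-fold lower (log2 -4.04, SE 0.229). Called probes occurred at every brightness, with 6.82% of the dimmest, 8.53% and 11.97% of the middle and 7.21% of the brightest of 4 equal brightness classes.

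**Figure D3:**
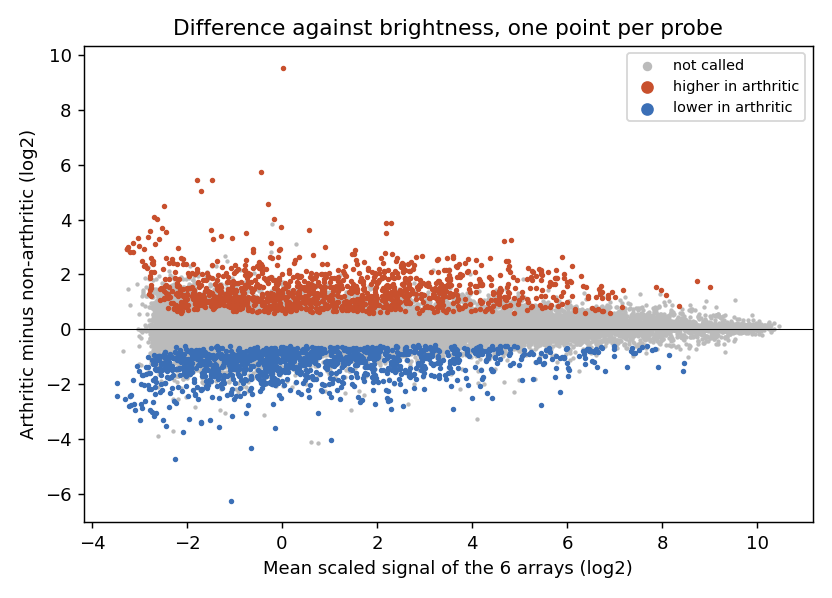
Difference between arthritic and non-arthritic mice (log2, vertical axis) against the mean log2 scaled signal of the 6 arrays (horizontal axis), with 1 point per probe tested; for probes not well above background in 1 group the plotted difference is the fitted value, not a bound. Orange marks the 1209 probes higher and blue the 1196 lower in arthritic mice at a limma adjusted p under 0.05.

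The test was limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over the 27869 probes. At an unadjusted p under 0.05 there were 3636 probes higher and 3222 lower. In 39.4% of all probes, and in all 2405 called probes, the 2 groups did not overlap. Chance gives 10% for a single probe. Probes are not independent across the 6 arrays, so the share over all probes can lie far from 10% by chance. That share was not obtained for other groupings of the arrays, so the 39.4% is not a test. With normexp background correction of the median signals the counts were 1932 higher and 776 lower, so that 71.3% of calls were higher, against 50.3%. There 1542 of the 2405 called probes were called again in the same direction, and 1 had the opposite sign. The counts also moved with each array left out. Without non-arthritic mouse 1 they were 5032 higher and 6225 lower. Of these, 993 and 1189 were at least 2-fold by the fitted differences, against 879 and 763 with all 6 arrays. Without that mouse, 2404 of the 2405 called probes were called again in the same direction. The remaining arrays were also part of the first fit, so this is not a replication. Leaving out non-arthritic mouse 2 gave 597 higher and 360 lower, and leaving out non-arthritic mouse 3 gave 554 and 382. Leaving out arthritic mouse 1, 2 or 3 gave 175 and 117, 214 and 149, and 198 and 145. Far fewer of the 2405 called probes were called again in these fits. The numbers were 932 and 923 without non-arthritic mice 2 and 3, and 292, 363 and 342 without arthritic mice 1, 2 and 3. With any of these last 5 arrays left out, the log2 differences correlated at 0.972 to 0.988 with those of all 6 arrays. Without non-arthritic mouse 1 the correlation was 0.891. Each such fit shares 5 arrays with the fit of all 6, so high correlations are partly built in. With any array left out the 2405 called probes could not change sign, because their groups did not overlap. All 6 arrays shared 1 slide and 1 scan, with the non-arthritic mice and arthritic mouse 1 in its first row and arthritic mice 2 and 3 in the other. With the row as a block, the log2 differences correlated at 0.956 with those of the unblocked fit. The unblocked differences include the same arrays, so this correlation is partly built in. The median SE rose from 0.25 to 0.39 with the block. In the blocked fit, 1 probe was called higher and 0 lower (3096 at an unadjusted p under 0.05). Both that fit and a fit within the first row (1 higher, 0 lower, 1876 at an unadjusted p under 0.05) draw the contrast from arthritic mouse 1 against the 3 non-arthritic mice, so they give the same differences and are not independent of each other.

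**Figure D4:**
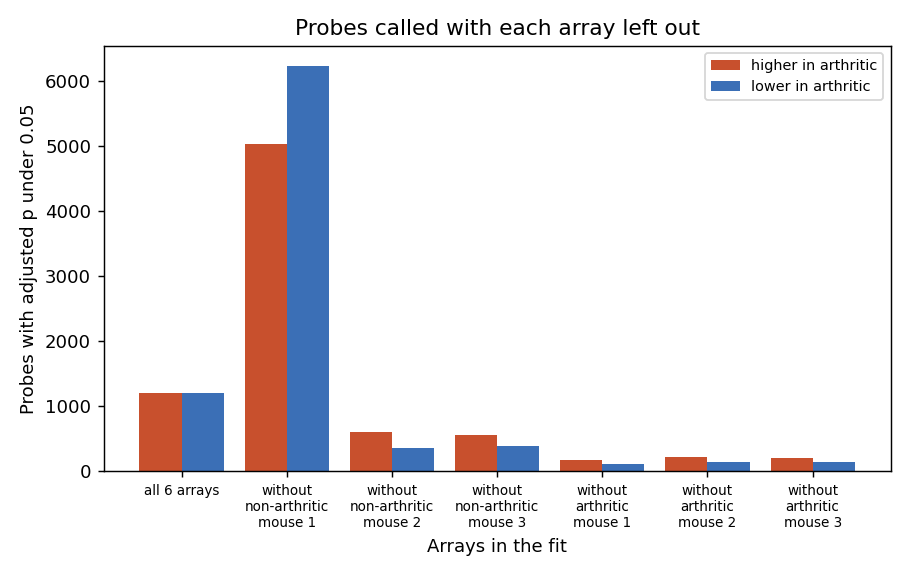
Number of probes with a limma adjusted p under 0.05 (vertical axis) that were higher (orange) or lower (blue) in arthritic mice, with all 6 arrays and with each array left out (horizontal axis). The counts are 1209 and 1196 with all arrays and 5032 and 6225 without non-arthritic mouse 1, while leaving out any other array lowers both. Without non-arthritic mouse 1, 993 higher and 1189 lower called probes were at least 2-fold by fitted differences, against 879 and 763 with all arrays.

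Probes were also grouped into 7 families by their IDs, and called probes were found in each of them. Among the 13655 probes of the authors' value table, 600 were higher and 635 lower. Of 11843 other ASMM9PARTA probes, 510 were higher and 482 lower. The share of probes detected, and so tested, was 36.5% for MM9LINCRNAEXON, 20.4% for mouselincRNA and 18.6% for humanlincRNA, whose IDs name long intergenic noncoding RNA (lincRNA). It was 32.2% for GenBank-named probes and, with the probes of the value table counted by their IDs because that table holds detected probes only, 49.1% for ASMM9PARTA and 30.9% for CUST probes. Of 1263 MM9LINCRNAEXON probes 60 were higher and 48 lower, of 141 mouselincRNA probes 3 and 2, and of 227 humanlincRNA probes 7 and 2. Among 351 CUST probes 15 were higher and 13 lower, and among 389 probes named by a GenBank accession 14 and 14. With adjustment over the family alone, the counts were 613 and 654 for the value table, 493 and 467 for the other ASMM9PARTA probes and 6 and 2 for humanlincRNA, and those of the other 4 families did not move.

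No family differed from the remaining probes as a whole in limma's camera test with a preset correlation of 0.01: 0 of 7 passed an adjusted p of 0.05, and 1, humanlincRNA, had an unadjusted p under 0.05 (0.0141, adjusted p = 0.0985, median log2 difference 0.22). With an estimated correlation the adjusted p was 0.874 for every family, and limma's fry gave adjusted p values of 0.839 or more for a shift in one direction. For changes in either direction, which fry tests without comparing a family with other probes, all 7 families passed, with adjusted p values from 0.000318 to 0.0128. With only probes well above background on all 6 arrays, humanlincRNA passed camera (adjusted p = 0.0199, median log2 difference 0.22), and over all settings in which families could be tested its adjusted p ranged from 0.0199 to 0.887. The median log2 differences of the families lay between 0.02 and 0.22, and those of the value table, other ASMM9PARTA, humanlincRNA and CUST probes changed sign under at least 1 other background correction or scaling. Without non-arthritic mouse 1, the medians were -0.015 for the value table, -0.058 for other ASMM9PARTA, -0.089 for CUST and -0.019 for GenBank-named probes, and they fell from 0.15 to 0.0088 for MM9LINCRNAEXON, from 0.16 to 0.065 for mouselincRNA and from 0.22 to 0.080 for humanlincRNA (camera adjusted p = 0.183 for the last). Camera gave the value table and CUST probes a downward direction although their means and medians were above 0. Of the lincRNA probes together, 7.48% were called, against 8.70% of the others (odds ratio 0.848, 95% interval 0.696 to 1.03, Fisher's exact test, two-sided p = 0.0926), a difference that did not pass and that treats probes as independent. By family the shares were 8.55% for MM9LINCRNAEXON, 3.55% for mouselincRNA and 3.965% for humanlincRNA (Fisher's exact test, adjusted p = 0.959, 0.0779 and 0.0557). Without non-arthritic mouse 1 the shares were 29.9% and 41.0% (odds ratio 0.613, 95% interval 0.549 to 0.684), with 34.4% for MM9LINCRNAEXON, 16.3% for mouselincRNA and 13.7% for humanlincRNA, against 42.3% for the value table, 39.9% for other ASMM9PARTA, 39.6% for CUST and 34.5% for GenBank-named probes.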

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

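The tests of a brightness offset and of other splits for the called probes were chosen only after the results had been seen, as were the values of control spots and of probes at least 4-fold apart. Among 56 control probe names, which no comparison used, 2 were well above background on all 6 arrays, and both had a higher signal in every arthritic mouse than in any non-arthritic mouse. The bright corner marker of the array, GE_BrightCorner, was 0.648 higher on the log2 scale (7.59 ± 0.133 against 6.94 ± 0.255, SD, n = 3 each). The control ERCC-00062_278 was 0.353 higher (-1.05 ± 0.081 against -1.40 ± 0.303, SD, n = 3 each). The exact permutation p was 0.1 for both, the smallest that 3 against 3 arrays allow, and without scaling the differences were 0.722 and 0.427. A technical difference between the groups is therefore not excluded, and its part in the called probes was not tested.

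Non-arthritic mouse 1 stood apart from the other arrays: 22.7% of detected probes differed at least 2-fold between it and the mean of non-arthritic mice 2 and 3, while 3.62% differed so between mice 2 and 3. The tables argue against an offset in brightness as the whole cause, since 17.9% still differed so after the trend of its deviation on brightness was removed, against 3.63% between mice 2 and 3 treated alike, although the direction depended on it (2263 higher and 4050 lower before, 3392 and 1601 after). They argue against a spatial artefact left after detrending within the array, since position in 128 blocks accounted for 3.52% of the variance of its deviation. For the difference between mice 3 and 2, position accounted for 14.7%. The tables also argue against noise of dim probes. In the brightest of 4 equal classes of probes, the smaller of the SDs of difference of non-arthritic mouse 1 was 3.52 times that between mice 2 and 3. A mislabelled arthritic mouse would lie near 1 on a scale from non-arthritic mice 2 and 3 (0) to the arthritic mice (1), but its median was 0.0966 over 11257 probes, with quartiles of -0.92 and 1.22, and 0.0603 over 344 probes at least 4-fold apart, with quartiles of -0.245 and 0.384. A difference in the animal, its cell preparation or its RNA stays open and was not tested.

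Of the 10 splits of the 6 arrays into 3 and 3, the real one called 2405 probes and the highest of the other splits called 0, and 1 split, the real one, reached the real count. Every other split mixes arthritic and non-arthritic mice, so any difference between the groups, biological or technical, adds to the spread it is tested against. The 0 calls of the other splits are therefore no evidence on the cause of the calls. For families, the real split had 0 past the threshold, all 10 splits had as many, and the highest other had 6; the preset correlation of 0.01 lay below the estimates of 0.0347 to 0.245 within families, which were made for the real split. With 10 splits no share under 0.05 can be reached.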

How the results depend on the processing

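The alternatives named as added, the families and the array row were chosen after the data had been seen. The counts of probes higher and lower stayed within 1.5 times 1209 and 1196 with quantile normalization, median scaling, a filter on all 6 arrays, an intensity trend, robust variance and flagged spots as missing. On the 13655 probes of the authors' value table they were 899 and 841 (12.7% called), where the main values gave 600 and 635 (9.04%). They were 1932 and 776 with normexp on the median signals (added), which moved the share of higher calls from 50.3% to 71.3%. They were 2027 and 1904 with cyclic loess (added), 765 and 631 with no filter, where more probes are tested, and 5508 and 6818 with array weights. They were 1 and 0 both with the array row as a block and within the array row of both groups (added), where the contrast comes from 1 arthritic array, assumed to vary like the others. A 2-fold threshold on the fitted differences left 879 higher and 763 lower. With probes not well above background in 1 group at their bound, it left 841 and 673. With each array left out the counts ranged from 175 to 5032 higher and from 117 to 6225 lower. Leaving out non-arthritic mouse 1 gave the highest counts, with a median SE of 0.09 against 0.25. The cause of these changes was not tested. Families past the threshold were 0 except for 1 with probes well above background on all 6 arrays. The replicate block gave 525 higher and 386 lower; deviations of mice with the same number correlated at 0.0397, 0.295 and 0.236, so the numbers were not taken to pair the mice, although every mouse correlated best with its own number, a hint from the data and not the design. None of the 4 named probes changed sign. With arrays left out, the replicate block or the array row settings this was fixed in advance, because their groups did not overlap. Their tests kept their side of the threshold in 67 cases and lost it in 6, all under the array row settings. With each array left out, family medians ranged from -0.015 to 0.044 for the value table, -0.058 to 0.156 for other ASMM9PARTA, -0.089 to 0.095 for CUST and -0.019 to 0.236 for GenBank-named probes. Family medians changed sign, never with an adjusted p under 0.05, in 16 cases. For the value table they were -0.0067 with normexp, -0.015 with quantile normalization, -0.0097 with median scaling, -0.059 with cyclic loess and -0.017 with array weights, and without non-arthritic mouse 1 -0.015. For other ASMM9PARTA probes they were -0.0034 with cyclic loess, -0.058 with array weights and -0.058 without that mouse. For CUST probes they were -0.022 with normexp, -0.028 with cyclic loess, -0.093 with array weights and -0.089 without that mouse. For humanlincRNA the median was -0.0016 with normexp, and for GenBank-named probes -0.0013 with array weights and -0.019 without that mouse. The mean over probes of a gene and normexp on mean signals were not run, and families could not be tested on the value table, which holds 1 family. Camera itself uses no trend, robust variance or array weights. Signal over background limits the probes of the lowest signals to bounds.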

Other observations

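The tests by lincRNA family were chosen only after the results had been seen; the other tests were written before, although the correlation of opposite strands and the lower share of lincRNA calls had been noticed first. Many lincRNA probes come in pairs that read opposite strands of one locus by their IDs. Of 2676 such pairs, 261 had both probes detected, 1108 had 1 detected and 1307 had none. Within families the pairs with both detected were close to what independent detection would give: 224 against 229 for MM9LINCRNAEXON, 12 against 14.4 for mouselincRNA and 25 against 21.1 for humanlincRNA. The deviation of non-arthritic mouse 1 from mouse 2 correlated at -0.0251 across probes with the difference between the arthritic mice and mouse 3, and with mice 2 and 3 exchanged at -0.0075.

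The log2 differences of the 2 probes of a pair correlated weakly over the 261 pairs (Pearson 0.142, Spearman 0.201), across probes, which are not independent replicates. Against 10000 draws of random pairs of the same family and brightness, 98.37% lay below the observed value, which does not decide whether a shift shared by dim probes of a family may account for it. Without non-arthritic mouse 1 the correlation was 0.161 and 99.66% of matched draws lay below it, which argues against the deviation of that mouse as the source. In 45 pairs 1 probe was called, and in the 1 pair with both called the directions were opposite. Transcription from both strands of one locus stays a hypothesis, and signal of one transcript on both probes was not tested.

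Without non-arthritic mouse 1, 29.9% of lincRNA probes were called, against 41.0% of other probes. LincRNA probes were dimmer, with a median log2 scaled signal of -0.777 against 0.262. Random sets of other probes matched on brightness in 20 bins had a median of 35.9% called (95% of draws between 33.8% and 38.1%). The observed share lay at percentile 0 of 10000 draws. Dim probes being called less often could thus account for at least part of the gap. The draws treat probes as independent, while correlations estimated with all 6 arrays were 0.245, 0.1355 and 0.1815 within MM9LINCRNAEXON, mouselincRNA and humanlincRNA. The spread of the draws may therefore be too narrow, and the percentiles do not decide whether dimness accounts for the whole gap, together or by family. With all 6 arrays the share of 7.48% lay at percentile 4.21 of matched draws, between 7.30% and 9.87% for 95% of them. By family, the share called lay at percentile 0 of matched draws for mouselincRNA (16.3%, matched median 31.9%) and humanlincRNA (13.7%, matched median 31.3%). For MM9LINCRNAEXON it lay at percentile 1.01 (34.4%, matched median 37.3%), which does not decide whether dim probes being called less often accounts for its gap. The gap was not seen with every array left out: the shares were 3.56% and 3.43% without non-arthritic mouse 2 and 1.104% and 1.044% without arthritic mouse 1. What accounts for the gap stays open.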
